A study of Caenorhabditis elegans with 2 samples.

How the data were processed

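The data were transcription factor ChIP-seq peak lists from whole late embryos of Caenorhabditis elegans. Per the labels, the strain carries an integrated construct in which the promoter of ttr-39 drives UNC-55a fused to GFP, together with dpy-20 as a marker. Per the labels, 2 biological replicates were made. The antibody is given in the labels only as unc-55, and the tag as GFP in the genotype but as GFP with FLAG in a note. The replicates form 1 group, so no comparison between groups was made. The control library that the deposited lists were called against was not analysed here.

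The deposited files were peak lists in ce11 and in ce10 coordinates. Per the descriptions deposited with the lists, regions were called against a control in replicate 1, in replicate 2 and in the pooled alignments of both. The authors then kept an optimal set by the irreproducible discovery rate (IDR), a measure of how well ranks repeat between lists. Which lists were compared for this set is not known here. A peak of this set need not lie in each replicate's own list: replicate 1's list overlapped 770 of the 2511. All 2511 were the strongest regions of the pooled list, so membership alone does not show that a peak repeats between replicates. The peak caller, the aligner and their versions are not given in the sources used here. Each region carries a signal value set by the authors' peak caller against the control, which is not scaled between lists. It was used here only to describe, rank and filter regions within a list. The deposited q-value, given as −log10, held 1 value for every region of the IDR set and of replicate 1's list, so regions were not ranked by it. The summit position, also the authors' own, was used to place each peak. No read counts were analysed here, so the depth of either library is unknown, and intervals cover counting error over peaks or genes only.

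The ce11 lists were the main data and were compared with the WBcel235 genome sequence and the Ensembl gene annotation of that build. Every region ended within the length of its chromosome. Positions are given 1-based. Near-identical genes, such as histone and chemoreceptor copies that share a symbol, were kept as separate genes, and binding of a single copy is uncertain because it depends on how the authors' alignment treated shared reads. Operons were not treated separately, and a summit in the windows of more than 1 gene counted for each.

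An overlap was at least 1 shared base pair. A promoter window ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, and a gene was bound if its window held an IDR summit. Summits outside these windows were classed in order as exonic, intronic, within 1000 bp 3′ of a gene or other intergenic. Shares have 95% Wilson intervals. Locations were compared with 1000 random placements on the same chromosomes. Each of 23 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, and with 10000 random lists matched in 10 bins of the distance to the upstream neighbouring gene. Sequences within 100 bp of a summit were compared with a window 1000 bp away, on a side drawn by seed, by the exact McNemar test, two-sided, for 4 preset motifs and for 2080 6-mer pairs, each a 6-mer and its reverse complement. Trends with signal used a permutation test of Spearman's rho with 100000 resamples, two-sided. Peaks and genes are not replicates, so these p-values describe this peak set and not the spread between embryos or cultures.

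The lists, tests and alternatives were fixed before the data were examined, as was the rule for named genes, except where a later choice is stated. That rule took the genes at the 15 strongest IDR peaks (the gene whose promoter window held the summit, otherwise the gene with the nearest transcript start), every member of the lists of construct genes, D neuron remodelling and GABA neuron identity, and the strongest bound members of each other list, 4 where its adjusted p was under 0.05 and 2 otherwise. The member elt-5 of the epidermal list was not found in the annotation by that name. Alternatives were the stronger part of the IDR set, the top peaks of each replicate alone, other overlaps, windows, flanks and gene backgrounds, and the ce10 lists. Alternatives restricted to IDR peaks overlapped by replicate 1, or to the strongest summit within 300 bp, were chosen after seeing the data. Mitochondrial regions were left out of sequence and location tests.

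The tests were tested on simulated data. Of 10 6-mers planted in flanking windows of the IDR peaks, 9 were recovered against other flanking windows. With nothing planted, 0 of 2080 6-mer pairs were called between flanking windows. No summit window was used, and the difference in GC content between summits and flanks was not simulated. The error of the 6-mer test under such a difference is therefore not known. Of 12 gene lists with planted binding, 12 were recovered, and 1 of 12 lists drawn at random was called. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.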

Results

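Binding of UNC-55, a nuclear receptor of the COUP-TF family that acts in the VD motor neurons, was mapped by ChIP-seq in late embryos of a strain expressing a GFP fusion. The lists of replicates 1 and 2 held 3577 and 30000 regions, the pooled list 30000, and the IDR set 2511 peaks. The pooled list is labelled by the authors as peaks and background. It and replicate 2's list held exactly 30000 regions in ce10 also. Their smallest −log10 q-values in ce11 were 0.0322 and 0.0272, so 30000 is not a count of bound sites. The labels name the antibody only by its target, UNC-55, and give the tag as GFP in one place and as GFP with FLAG in another, so whether the tag or the receptor itself was pulled down is not known here. Whole embryos were used, and per the labels the ttr-39 promoter drove the fusion. Which cells the peaks come from, and whether those cells normally make UNC-55, is not known here. The depth of the libraries is unknown.

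The first question was how far the replicates share the IDR peaks. The sites at unc-62 and ceh-20, which encode homeodomain proteins of the MEIS and PBC classes, ranked among the strongest in both replicates: the unc-62 peak of rank 1 in the IDR set overlapped regions of rank 10 in replicate 1 and rank 1 in replicate 2, and the ceh-20 peak overlapped regions of rank 11 and rank 4. Across the set, replicate 2's list overlapped 2510 of the 2511 IDR peaks, and replicate 1's list overlapped 770, or 30.7% (95% Wilson interval 28.9 to 32.5). Whether both lists were called with the same settings is not given in the sources used here: replicate 1's regions had a median width of 284 bp and 1 −log10 q-value, 2.36, and replicate 2's a median width of 360 bp and −log10 q-values from 0.0272 to 4.05, so the share also depends on where each list ends. With each list ended at its 2511 strongest regions, the overlaps were 637 for replicate 1 and 2345 for replicate 2. When replicate 1's regions were placed at random, they overlapped 57.4 IDR peaks on average and at most 74 in 100 draws. All 2511 IDR peaks were the 2511 strongest regions of the pooled list. The share of replicate 2's regions overlapped by replicate 1 was 66% (56.3 to 74.5) for ranks 1 to 100 and 2.64% (2.34 to 2.97) for ranks 20001 to 30000. In the pooled list, which was called on the data of both replicates and so is not independent of replicate 1, the shares were 70% (60.4 to 78.1) and 3.90% (3.54 to 4.30). Across the 770 peaks overlapped by both replicates, Spearman's rho between their signal values was 0.24, a correlation across peaks, which are not independent replicates.

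**Figure D1:**
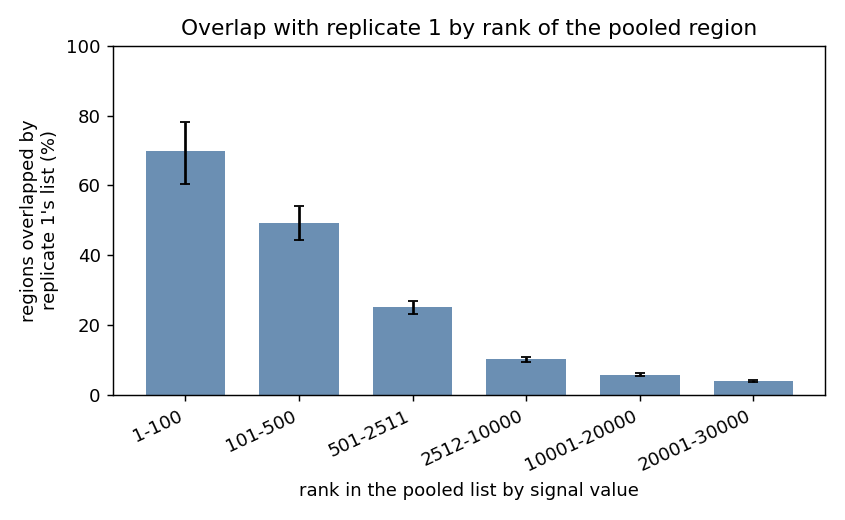
Share of pooled regions (%) overlapped by replicate 1's list, by rank of the pooled region's signal value; bars are shares and error bars 95% Wilson intervals. The pooled data include replicate 1; the share falls from 70% in ranks 1 to 100 to 3.90% in ranks 20001 to 30000.

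By nearest transcript start, 3 of the 5 strongest peaks fell to unc-62, 1 to ceh-20 and 1 to M106.2. The M106.2 peak, of rank 3 with a signal value of 264.2, was intergenic. In replicate 1's list, the regions of rank 1 and rank 2 overlapped the peaks nearest M106.2 and Y111B2A.12. The peak of rank 1, with a signal value of 321, lay on chromosome V from 4507800 to 4508190 (ce11), with its summit in an annotated 5′ UTR of unc-62. The peak of rank 2, with a signal value of 310, lay on V from 4491262 to 4491633, in intergenic sequence. Its summit was at -5997 bp relative to the nearest transcript start, that of unc-62. It lay outside the 5000 bp counted below and within 5000 bp of exc-15, and overlapped a region of rank 47 in replicate 1's list. The peak of rank 4, with a signal value of 227, lay on V from 4499351 to 4499799, in a 5′ UTR of unc-62. Within 5000 bp of the gene there were 10 IDR summits, more than at any other protein-coding gene, followed by 7 at egl-27. The span counted includes the gene itself, 13989 bp for unc-62; per kb of gene and flanks, among genes with at least 4 summits, hmg-1.1 and Y54G11A.2 had more, 0.558 and 0.450 against 0.417. The genes egl-27, hmg-1.1, Y54G11A.2 and exc-15 were named after their counts or positions were seen. The ceh-20 peak of rank 5, with a signal value of 225, lay on III from 6978985 to 6979288, with its summit at -746 bp relative to the transcript start. Other genes at the 15 strongest peaks were Y111B2A.12, Y43F8B.2, casc-3, T23G4.127, ttr-17, pigx-1, sma-9, zfp-1, ndx-1 and T28F4.1. Of these, Y43F8B.2 and zfp-1 had the summit in a promoter window, and the peaks nearest ttr-17, pigx-1 and T28F4.1 were not overlapped by replicate 1's list.

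**Figure D2:**
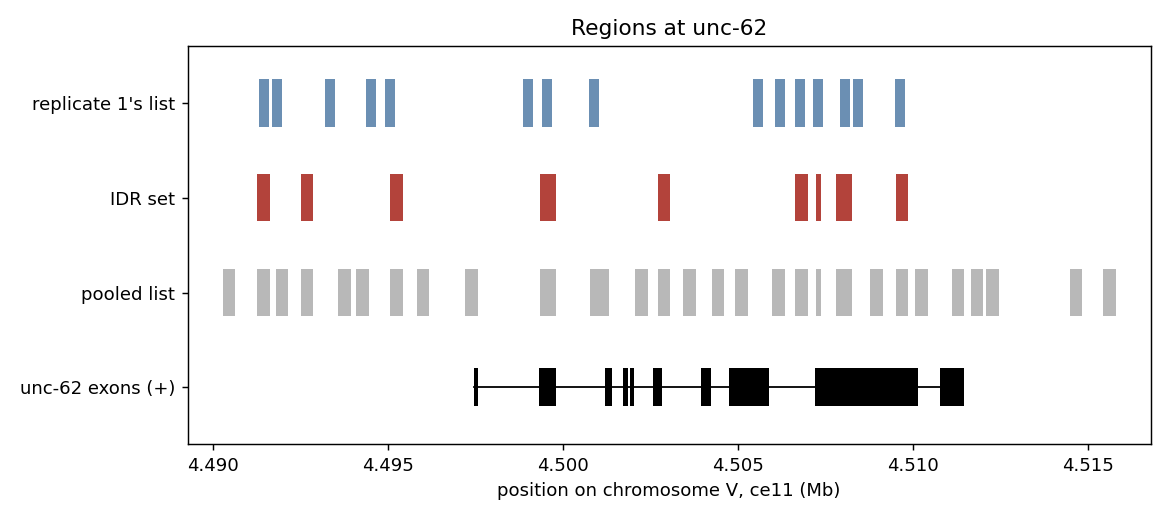
Map of unc-62 on chromosome V (ce11, position in Mb), with exons of all annotated transcripts in black, regions of the pooled list in grey, IDR peaks in red and regions of replicate 1's list in blue. The IDR peaks lie upstream of the gene and within it.

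The next question was where the peaks lie relative to genes. Promoter windows held 1225 of the 2511 IDR summits, or 48.8% (46.8 to 50.7), against a mean of 25.6% and a maximum of 28.95% in random placements. Exons outside promoter windows held 34 summits, or 1.35% (0.971 to 1.89), against 21.8% at random. Introns held 471 summits, or 18.8% (17.3 to 20.3), against 27.7%, and other intergenic sequence held 639, or 25.4% (23.8 to 27.2), against 19.3%. Each of these differences had a two-sided p of 0.002 by random placement, the smallest that 1000 placements can give. The 142 summits within 1000 bp 3′ of a gene, 5.66% (4.82 to 6.63), lay inside the range of 4.34% to 7.65% in random placements. Among the 2511 weakest pooled regions, from a list labelled as peaks and background, promoter windows held 29.1%. With the top peaks of replicate 1 alone, the promoter share was 36.0%.

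Promoter binding was then compared between gene lists. In all, 1466 of 19973 protein-coding genes (7.34%) were bound. With the chosen window, genes of cytosolic ribosomal proteins were bound most often, 52 of 79 (65.8%, 54.8 to 75.3; odds ratio 25.2, Fisher's exact test, adjusted p = 1.48e-38), with rpl-25.2, rpl-3, rps-19 and rpl-15 at signal values of 66.5, 62.1, 61.0 and 55.05. Of the 52 genes, 12 had a peak overlapped by replicate 1's list. With the top peaks of replicate 1 alone the list had 12 of 79 bound (odds ratio 3.34, Fisher's exact test, adjusted p = 0.00492), and with each summit given to its nearest transcript start only, 31 of 79 (odds ratio 5.85), the adjusted p ranging from 1.16e-40 to 0.00492 over the alternatives. Body wall muscle genes followed with 14 of 29 (48.3%, 31.4 to 65.6; odds ratio 11.9, Fisher's exact test, adjusted p = 2.58e-08). They included unc-112, a component of muscle attachment sites, hlh-1, the worm MyoD homologue, pat-10, a troponin C, and pat-3, an integrin subunit, at signal values of 78.3, 75.8, 54.2 and 47.8. Only 3 of these 14 genes had a peak overlapped by replicate 1's list, and with such peaks alone the odds ratio was 5.27 and the adjusted p 0.0786 (Fisher's exact test). With the top peaks of replicate 1 alone the list had 7 bound (odds ratio 5.92, adjusted p = 0.00492), and the smallest adjusted p over the alternatives was 2.28e-14 (Fisher's exact test). The order of the lists turned with these choices: muscle genes stood above ribosomal protein genes with nearest starts only (21 of 29, odds ratio 23.7), with a window from 2000 bp upstream to 500 bp downstream (21 of 29, odds ratio 23.1, against 55 of 79, odds ratio 20.5) and with replicate 1's top peaks, where pan-neuronal genes had the largest share, 6 of 23.

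Other housekeeping lists were also bound more often. The proteasome list had 9 of 33 genes bound (odds ratio 4.76, Fisher's exact test, adjusted p = 0.00187), led by rpn-5, rpn-3, rpn-9 and pbs-1 at signal values of 83.5, 73.2, 36.3 and 32.7. The heat shock list had 7 of 22 (odds ratio 5.91, Fisher's exact test, adjusted p = 0.00237), led by hsp-110, hsp-3, hsp-1 and hsp-90 at 73.2, 66.6, 63.8 and 51.6. The summit at hsp-110 also lies in the window of rpn-3. When each summit was given to its nearest transcript start only, the adjusted p was 0.0982 for the proteasome and 0.416 for heat shock proteins, and in the stronger part of the IDR set it was 0.235 for the proteasome (Fisher's exact test). Over all alternatives it ranged from 0.000873 to 0.235 for the proteasome and from 0.000635 to 0.416 for heat shock proteins.

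Among the lists of neuronal genes, the pan-neuronal list had 7 of 23 genes bound (odds ratio 5.54, Fisher's exact test, adjusted p = 0.0028), including unc-108, snb-1, syd-2 and unc-33 at signal values of 51.5, 43.8, 38.5 and 34.2; snb-1 encodes synaptobrevin. The axon guidance list had 6 of 27 (odds ratio 3.62, Fisher's exact test, adjusted p = 0.0307), including unc-40, the netrin receptor, unc-73, mig-10 and sax-7 at 45.8, 45.4, 36.2 and 34.2. With a window from 500 bp upstream to 100 bp downstream, the adjusted p was 0.293 for the pan-neuronal list and 0.945 for axon guidance (Fisher's exact test). With a window from 2000 bp upstream to 500 bp downstream it was 0.000873 and 0.000817, and with nearest starts only the lists had 11 of 23 and 16 of 27 genes bound (Fisher's exact test, adjusted p = 2.05e-05 and 2.64e-09, the smallest over the alternatives). With the top peaks of replicate 1 alone it was 0.00492 for the pan-neuronal list (odds ratio 6.56) and 0.134 for axon guidance (odds ratio 3.22). The D neuron remodelling list had 4 of 15 (odds ratio 4.60, Fisher's exact test, adjusted p = 0.0472). Its bound members were pde-4, myrf-2, cdk-5 and myrf-1, at signal values of 37.5, 31.9, 28.7 and 26.1, and 0 of the 4 peaks were overlapped by replicate 1's list. Its unbound members were flp-13, irx-1, unc-8, hbl-1, oig-1, lin-14, dve-1, unc-30, cyy-1, ced-3 and gsnl-1. Of these, lin-14, hbl-1 and cyy-1 each had 2 IDR summits within 5000 bp of the gene, so unbound means only that no summit lay in a promoter window. Against random lists matched on upstream distance the adjusted p for this list was 0.0851, and it was 0.215 and 0.341 with the top peaks of replicate 2 and of replicate 1 alone. The call held with nearest starts only (6 of 15, adjusted p = 0.00758, Fisher's exact test) and with the narrower and wider windows (adjusted p = 0.0213 and 0.0299), so it depended on these choices. The GABA neuron identity list had 2 of 8 genes bound, gta-1 and snf-11, at 42.9 and 35.9 (adjusted p = 0.198, Fisher's exact test). Its members unc-25, unc-47, unc-46, unc-30, lim-6 and alr-1 were not bound, though lim-6 had 1 IDR summit within 5000 bp. The cholinergic identity list had 0 of 10 (adjusted p = 1, Fisher's exact test), though 3 of the 10 genes had an IDR summit within 5000 bp.

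Chemoreceptor, collagen and neuropeptide genes were bound less often than other genes. The counts were 9 of 1309 chemoreceptor genes (odds ratio 0.0818, Fisher's exact test, adjusted p = 1.88e-31), 1 of 173 cuticle collagens (odds ratio 0.0728, adjusted p = 0.000287) and 1 of 140 neuropeptide genes (odds ratio 0.0902, adjusted p = 0.00187). The bound members with the largest signal values were srh-2, sre-23, sri-5 and srr-10 at 75.9, 35.0, 34.3 and 32.7, col-38 at 36.1 and ins-39 at 24.6. The col-38 summit also lies in the window of rpl-5, which was named after its value was seen. With the top peaks of replicate 1 alone, 19 chemoreceptor genes were bound (odds ratio 0.259, Fisher's exact test, adjusted p = 1.82e-11), and the adjusted p was 0.258 for collagens, with 4 bound, and for neuropeptides, with 3 bound. Over the alternatives the adjusted p ranged from 3.02e-47 to 3.27e-08 for chemoreceptors, from 4.23e-06 to 0.258 for collagens and from 8.14e-05 to 0.258 for neuropeptides (Fisher's exact test).

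The other lists did not pass the threshold. Bound genes numbered 9 of 96 homeodomain factors (adjusted p = 0.659, Fisher's exact test), including unc-62 and ceh-20, 13 of 274 nuclear hormone receptors (adjusted p = 0.198), including nhr-119 and nhr-1 at signal values of 83.8 and 65.9, and 3 of 30 bHLH factors (adjusted p = 0.692), including hlh-1 and hlh-30 at 75.8 and 42.2. They numbered 9 of 72 histone genes (adjusted p = 0.198, Fisher's exact test), including the divergent pair his-67 and his-68 at 80.8, and 2 of 27 acetylcholine receptor subunits (adjusted p = 1), lev-8 and unc-38 at 28.9 and 27. They numbered 1 of 20 intestinal genes, erm-1 at 25.2, 1 of 16 germline genes, mex-1 at 46.1, 0 of 6 pharyngeal genes and 0 of 7 epidermal regulators (adjusted p = 1 for each, Fisher's exact test), and 0 of 26 ciliated neuron genes (adjusted p = 0.422). Of the 23 lists, 22 had the same call against the matched random lists, D neuron remodelling being the exception.

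**Figure D3:**
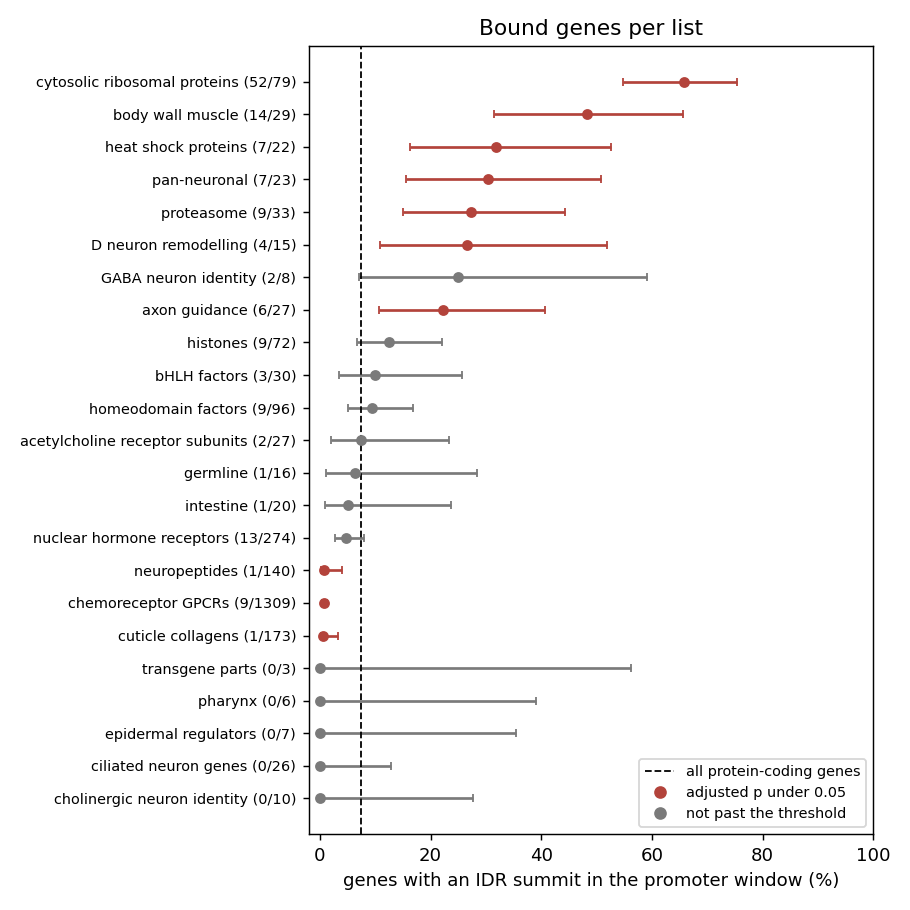
Share of genes (%) with an IDR summit in the promoter window, per list, with bound and total genes in brackets; points are shares, bars 95% Wilson intervals, the dashed line all protein-coding genes (7.34%), and red marks an adjusted p under 0.05. Ribosomal protein genes lie highest, at 65.8%.

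Members of the COUP-TF family bind AGGTCA sites, and the sequence at the summits was examined for this motif. AGGTCA lay within 100 bp of 6.33% (5.44 to 7.35) of the 2511 summits and in 5.89% of the flanking windows. It was present only at the summit in 151 peaks and only in the flank in 140 (ratio 1.08, 95% interval 0.851 to 1.37, exact McNemar p = 0.558, adjusted over 4 motifs p = 0.744). The excess at summits was 0.438 percentage points and ranged from 0.121 to 1.71 over the alternatives, the largest in promoter peaks (ratio 1.40, 0.968 to 2.03, exact McNemar p = 0.0755); it was 1.23 with replicate 2's top peaks alone (exact McNemar p = 0.0682). The interval for the IDR peaks does not exclude a small excess. In the 2511 weakest pooled regions the ratio was 1.32 (1.01 to 1.74, exact McNemar p = 0.0407, not adjusted), so a ratio above 1 was not particular to the IDR peaks. The extended site AAGGTCA was in 1.31% of summits and 2.11% of flanks (exact McNemar p = 0.0375, adjusted p = 0.0751), and direct repeats of AGGTCA were found at 0 summits and in 0 flanks. TAATCC, the core recognised by UNC-30, was less frequent at summits, 3.94% against 6.85% (ratio 0.573, exact McNemar adjusted p = 4.03e-05), but not detectably so in replicate 1's nuclear regions, 6.40% against 6.65% (ratio 0.960, 0.792 to 1.16, exact McNemar p = 0.702). Summits had a higher mean GC content than flanks, as given below. The preset motifs were not compared in windows matched on GC content, so these values do not separate site use from base composition. The share of peaks with AGGTCA did not change detectably with signal (rho = 0.0049, permutation p = 0.81); it was 6.96% (5.05 to 9.52) in the fifth with the strongest peaks and 6.77% (4.89 to 9.32) in that with the weakest.

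Without a preset motif, 764 of 2080 6-mer pairs were more frequent at summits and 595 less frequent (adjusted p under 0.05). GAGAGA was in 51.6% (49.7 to 53.6) of summit windows and 13.3% of flanks (ratio of peaks with it in a single window 7.41, interval 6.25 to 8.85, exact McNemar adjusted p = 1.50e-178), and ACGCAG was in 27.4% and 3.86% (ratio 8.97, adjusted p = 7.63e-117). A- and T-rich 6-mers such as AAAATT were less frequent at summits, 27.04% against 60.7%. Summit windows had a mean GC content of 44.6% ± 6.13 (SD over 2511 windows) and flanks 36.1% ± 7.20. In the top peaks of replicate 1 alone the GAGAGA ratio was 2.18 (1.87 to 2.55), the ACGCAG ratio was 2.87 (2.22 to 3.73), with 9.92% of summits against 3.74% of flanks, and 193 pairs were more frequent at summits. In the 770 IDR peaks that replicate 1's list overlapped, a set chosen after seeing the data, the ratios were 7.64 (5.62 to 10.6) for GAGAGA and 12.3 (7.59 to 21.1) for ACGCAG.

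**Figure D4:**
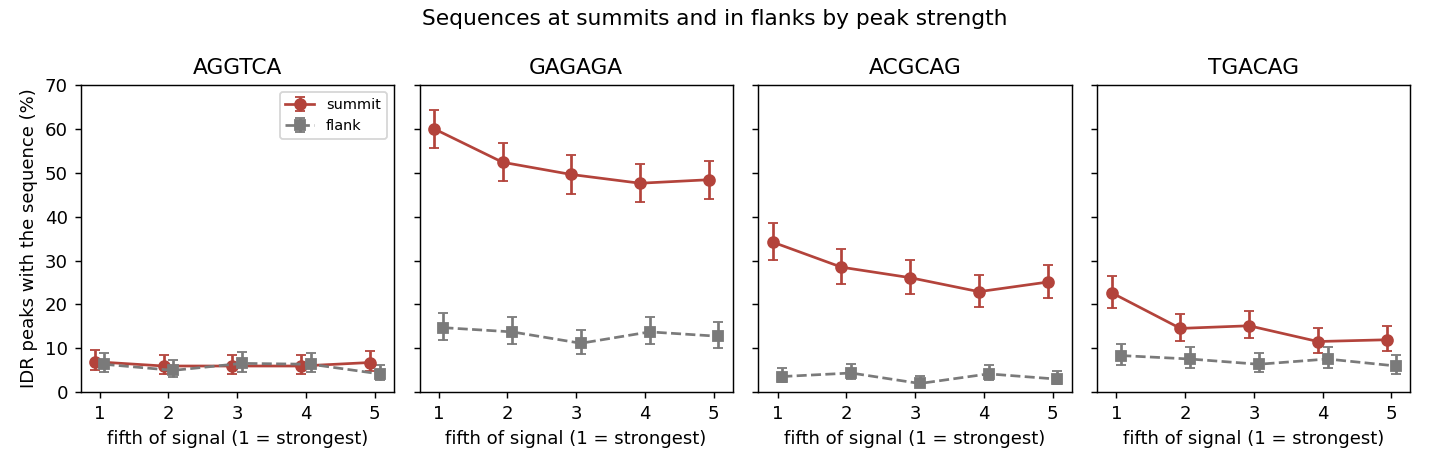
Share of IDR peaks (%) with each sequence within 100 bp of the summit (red) or in the flanking window (grey), by the fifth of signal value from strongest (1) to weakest (5); bars are 95% Wilson intervals. AGGTCA has overlapping intervals at summits and flanks in class 1, while GAGAGA is higher at summits there, 60.0% against 14.7%.

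The genes of the construct were examined as a check of the labels. No IDR peak overlapped unc-55, ttr-39 or dpy-20 or their 1000 bp upstream. At unc-55, on chromosome I from 7898434 to 7903334, the strongest pooled region had a signal value of 10.5 and rank 7981, and replicate 1's list had 0 regions. At ttr-39, on IV from 10088367 to 10089877, and at dpy-20, on IV from 11696430 to 11700852, the number of regions was 0 in every list. Since the control's strain is not known here, the result does not test whether the construct was present.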

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

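Replicate 1's list held 14 regions on the mitochondrial genome, a signal in data that the comparisons above do not use, and the other ce11 lists held 0. The strongest, from 2146 to 2429, had a signal value of 15.1 and rank 5 in that list. No explanation was tested.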

How the results depend on the processing

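No paired analysis was possible because the samples form 1 group. The excess of summits in promoter windows, the calls for ribosomal protein and chemoreceptor genes, and the absence of a call for AGGTCA at summits and for its trend with signal held under every alternative run, but not their sizes. The promoter share was lowest with replicate 1 alone, 36.0%, and was 37.3% and 65.4% with the narrower and wider window. With replicate 1 alone the odds ratio was 3.34 for ribosomal protein genes and 0.259 for chemoreceptors, against 25.2 and 0.0818. Values below for gene lists are Benjamini-Hochberg adjusted p-values of Fisher's exact test; the cause of each change was not tested, though several alternatives hold fewer peaks. In the stronger part of the IDR set, 3 lists were bound more often, and p was 0.676 for D neuron remodelling, 0.121 for pan-neuronal, 0.162 for axon guidance, 0.0874 for collagens and 0.235 for the proteasome. With 1 replicate's top peaks alone, p ranged from 0.215 to 0.341 for D neuron remodelling, 0.000238 to 0.258 for neuropeptides and for collagens, and 0.0313 to 0.134 for axon guidance; lists bound less often ranged from 1 to 3, 6-mer pairs higher at summits from 193 to 790 and lower from 94 to 582, the low ends being replicate 1 alone. With IDR peaks overlapped by replicate 1, an alternative chosen after seeing the data, 4 lists were bound more and 1 less often, 381 6-mer pairs were lower, and p was 1 for D neuron remodelling, with 0 of 15 genes bound where 0.323 were expected, which shows no direction, 0.182 for neuropeptides, 0.0758 for axon guidance, 0.0786 for body wall muscle, 0.145 for collagens, 0.0965 for the proteasome and 0.0209 for histones. With these 770 peaks the odds ratio was 4.57 for the proteasome and 5.71 for axon guidance, against 4.76 and 3.62 with all, so these calls were lost with fewer peaks at a similar or larger odds ratio; for body wall muscle it was 5.27 against 11.9. For neuropeptides 0 of 140 genes were bound where 3.04 were expected, and for collagens 0 of 173 where 3.76 were expected, so these lost calls do not show a smaller depletion. Ribosomal protein genes did not have the largest share of bound genes with nearest starts only, the wider window, replicate 1 alone or the IDR peaks it overlapped. With the window from 500 bp upstream to 100 bp downstream, p was 0.293 for pan-neuronal, 0.945 for axon guidance and 0.0409 for histones; with that from 2000 to 500 bp it was 0.0277 for nuclear hormone receptors, fewer of which were bound. With nearest starts only, p was 0.00758 for D neuron remodelling, 2.05e-05 for pan-neuronal and 2.64e-09 for axon guidance, whose calls held, and 0.0987 for neuropeptides, 0.0982 for the proteasome and 0.416 for heat shock proteins. Against genes with a public name, p was 0.103 for D neuron remodelling, 0.0925 for axon guidance and 0.0102 for nuclear hormone receptors. Depth is unknown, and the calling settings are not given, so it cannot be said whether replicate 1 has fewer regions because of fewer reads or another threshold.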

Other observations

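Genes without a protein product were compared with 1000 random placements of the IDR summits, a comparison chosen after the data were seen. Of 346 snoRNA genes, 41 had a summit within 200 bp, 8.61 times the random mean and above the highest placement, 12. For snRNA genes the number was 8, 5.36 times the mean, against a highest placement of 7. Pseudogenes and piRNA genes were near a summit less often, with 4 of 2128 against a random mean of 89.4 and 34 of 15363 against 139. For miRNA genes, 5 of 261 were near a summit, within the highest placement of 12. For long intergenic noncoding RNA genes the number was 17 of 194, 2.18 times the random mean but equal to the highest placement, 17. Chromosome I held 464 IDR peaks, 18.5% (17.01 to 20.04) of the set against 15.03% of the nuclear genome, chromosome X 526, 20.9% (19.4 to 22.6) against 17.7%, and chromosome III 402, 16.01% (14.6 to 17.5) against 13.7%. Chromosome IV held 376, 14.97% (13.6 to 16.4) against 17.4%, and chromosome V held 359, 14.3% (12.98 to 15.7) against 20.9%.

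Of the tests below, those on the strongest peaks, on replicate 1 as a weaker draw, on TGACAG and on the construct's genes were chosen only after the result was seen; no biological explanation that needs a comparison of groups was tested, since the samples form 1 group. The first pattern is that AGGTCA was not detectably more frequent at summits while GAGAGA was. GC content as the whole cause is argued against: in 438 pairs with a GC content within 3 percentage points, the summit-to-flank ratio of GAGAGA was 3.97 (2.72 to 5.93). The pairs were matched on GC content alone, so other differences in base composition stay open. GAGAGA had the smallest p of all 6-mers at these same summits, so its excess in a part of them is not independent evidence. Use of AGGTCA in the strongest peaks alone stays open, with a ratio of 1.10 (0.654 to 1.85) in the fifth with the strongest peaks. In the 100 strongest peaks AGGTCA was at 11% of summits and 6% of flanks, with a ratio of 2 and a wide interval (0.623 to 7.46). A pull-down of transcribed genes whatever the factor may contribute, since tRNA genes, which another polymerase transcribes, had a summit within 200 bp 3.98 times as often as at random, in 30 of 612 genes; with summits outside promoter windows alone, a check added later, the ratio was 5.81. The random placements were not matched on open chromatin, which is a further open explanation and was not tested.

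The second pattern is that replicate 1's list overlapped a minority of the IDR peaks. Of its 100 strongest nuclear regions, 63% (53.2 to 71.8) overlapped the 2511 strongest regions of replicate 2, and of its 100 weakest 21% (14.2 to 30.0), consistent with a weaker draw of the same sites. Its 1805 regions outside replicate 2's list had a promoter share of 27.9%, inside the range of 22.7% to 29.3% in random placements (mean 26.0%), so these may be largely background. The placements were matched on chromosome and not on lying outside replicate 2's list, so the comparison does not decide this. In these 1805 regions the summit-to-flank ratios were 0.977 (0.788 to 1.21) for GAGAGA, 1.09 (0.745 to 1.59) for ACGCAG and 1.30 (0.998 to 1.69) for TGACAG. In the IDR peaks they were 7.41, 8.97 and 2.15. The sequences were picked in the IDR peaks, so regions without them could still be bound. Both explanations stay open together, as does a list called with other settings, which was not tested.

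The third pattern is that 4 of the 5 strongest peaks were nearest the transcript starts of unc-62 and ceh-20, 1 of them at -5997 bp from that of unc-62. The other was nearest M106.2. In addition TGACAG, the core site of MEIS proteins such as UNC-62, was more frequent in stronger peaks (rho = 0.11). The trend was not particular to it, with rho = 0.083 for GAGAGA and 0.073 for ACGCAG. TGACAG was at 38% (29.1 to 47.8) of the 100 strongest summits and 8% of their flanks. Base composition stays open as the cause: among 180 6-mer pairs of the same bases, the ratio of TGACAG in the fifth with the strongest peaks stood at percentile 99.4, but it was chosen because it stood out in those peaks, so neither its rank, its trend nor its share there is independent evidence. A candidate explanation is that the libraries hold sites bound by UNC-62 or CEH-20, from a shared site or another strain; the number of IDR peaks over the 3 construct genes, 0, does not decide between them, because the control's strain is not known here.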
